A study of Rattus norvegicus with 20 samples.

How the data were processed

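RNA was measured in 20 libraries from the prefrontal cortex and nucleus accumbens of male Fischer344/Jcl rats, an inbred laboratory strain. Per the labels, rats received either the standard AIN-93G diet or a low-iron diet between 21 and 39 days of age, and tissue was taken at 13 weeks. Each region and diet was represented by 5 libraries. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. Per the labels' protocols, RNA with an integrity number above 8.3 was enriched for poly(A), made into libraries with a NEBNext Ultra kit and sequenced as 75 bp single reads on a NextSeq 500 after the 20 samples were pooled.

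The authors deposited read counts for each RefSeq accession in each library. The submitters' processing notes name Trimmomatic 0.36.3, STAR, HTSeq, DESeq2, DESeq and the rat build rn6, without saying which tool made which values. The unstranded count column was used. Reads split about evenly between the strand columns, with 49.6 to 50.0% on the first, so strand could not be used to separate a gene from an antisense partner. Features were 18288 accessions, of which 17617 were messenger and 671 non-coding. Names came from a RefSeq gene table of assembly GRCr8 for 17353 of them and from the authors' deposited tables for 859 more, which left 76 without a symbol. That assembly differs from rn6, so it served for names alone, and chromosomes are those in the authors' deposited tables. The deposited tables of the diet comparisons also hold log2 fold changes, a test statistic (score) and p-values made by the authors; their counts equalled those of the libraries for all 17026 accessions they contain. No count column lacked a sample.

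Rows of the count files that name no gene were left out of library sizes and tests. They held 50.8 to 60.7% of reads, mostly reads outside annotated features (35.3 to 44.2%). Reads mapped to several places took 8.10 to 9.09%, and ambiguous reads 3.61 to 4.23%; transcripts of the same gene are separate features, and 1585 accessions share a symbol with another. Assigned reads ranged from 4.34 to 12.97 M per library. An accession with 0 reads could hold up to 3 reads, or 0.231 to 0.691 CPM (counts scaled to library size) depending on the library; this floor and all intervals on reads cover counting error only. Of the 40 pairs of libraries within a group, the closest had a chi-square of 1.97 per degree of freedom over accessions with at least 20 reads, so no library was counted as a copy of another.

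Differences were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM normalization, robust dispersions and filterByExpr (minimum count 10). Adjusted p-values are Benjamini-Hochberg values over the accessions tested, and any adjusted p with no tool named is from edgeR. The standard error (SE) of a log2 fold change was the fold change divided by the square root of F. Each diet comparison used the 10 libraries of the region. The interaction of diet and region used all 20, and the region comparison used the 10 standard-diet libraries. DESeq2 1.42.0 was an alternative. Before the data were examined, 30 gene lists were fixed, of which 27 had at least 5 measured members and were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with prior count 2). The lists were tested again with an estimated correlation and with fry. Members were also adjusted over each of the 27 lists alone, in each comparison. Where no gene changes, about 1 list in 20 would hold such a pass by chance. Reln was tested alone with an exact permutation test on log2 CPM, two-sided, whose smallest p with 5 libraries against 5 is 0.00794.

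Named genes followed a rule fixed before the data were examined. Where fewer than 10 genes passed, the 5 genes with the lowest unadjusted p in each direction were named, with Reln, Vldlr, Lrp8 and Dab1, and the 2 members with the lowest p of each list discussed. Lrp8 is not analysed here. For the region comparison the rule took the 5 largest folds in each direction among genes whose groups did not overlap, with at least 10 CPM in the higher group; not all of these are reported here.

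The model was tested on simulated counts with 200 changed genes. In the accumbens simulation over 11202 accessions, edgeR recovered 93% of 2-fold changes and 76% of 1.5-fold changes, with 9 false calls, and DESeq2 94% and 79%, with 17 false calls. In the cortex simulation over 11662 accessions the shares were 93% and 68%, with 6 false calls, and for DESeq2 94% and 74%, with 14 false calls. These shares hold for data with that many changed genes, beside a further list shifted by less. Genes were drawn independently, so the simulation held no structure shared between genes across libraries, which real data can hold. Adjustment is stricter where few genes change, so a lack of calls does not show that 2-fold changes were absent. In the real accumbens data Reln, at 0.534-fold, had an edgeR adjusted p of 0.972. Alternatives were DESeq2, its size factors, no filter, robust estimation off, a replicate block, all 20 libraries in each diet fit, 1 surrogate variable (sva 3.50.0), for the correlation of fold changes a minimum of 10 CPM, and leaving out each library in turn. Summing accessions by gene symbol, a library-size covariate and leaving out each library for the interaction lists were added after the data were seen. Of the 126 ways to divide 10 libraries evenly, 100 were drawn, the real one included.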

Results

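The data were poly(A) RNA counts from 2 brain regions of adult rats that had eaten a low-iron or a standard diet for a period after weaning, with 5 libraries for each region and diet. The series title names reelin in the nucleus accumbens, a ventral striatal region, as the subject. Assigned reads were 7.19 ± 1.35 M (SD, n = 5) in standard-diet accumbens libraries and 5.13 ± 0.696 M (SD, n = 5) in low-iron ones. This difference had an exact permutation p of 0.0238, or 0.167 after adjustment over the 14 library measures compared. In the prefrontal cortex the standard-diet libraries held 10.3 ± 2.004 M and the low-iron libraries 9.36 ± 2.59 M (SD, n = 5).

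The first question was which genes differed with diet in the nucleus accumbens. Reln, which encodes the secreted glycoprotein reelin and lies on chromosome 4 of rn6, was at 20.5 ± 4.72 CPM in the low-iron libraries and 39.2 ± 9.65 CPM in the standard-diet libraries (SD, n = 5). All 5 low-iron libraries lay below all 5 standard-diet libraries, with a log2 fold change of -0.90 (SE 0.19), or 0.534-fold (95% interval 0.403 to 0.708). Between 65 and 322 reads per library supported these values. Standard-diet replicate 4 had the highest Reln level, at 54.7 CPM, and also the highest level of Slc17a7, a gene of cortical glutamatergic neurons. Slc17a7, chosen here after its values were seen, stood at 325 CPM there against at most 18.1 CPM in the other 9 accumbens libraries. Of the other measured cortical glutamatergic markers, Tbr1 (55.8 CPM), Nrn1 (58.0) and Nptx1 (146) were also highest in replicate 4. Fezf2 (3.85 CPM there), Cux2 (63.9), Rorb, Lmo4, Ccn2 and Foxp2 were highest in other libraries. Without standard-diet replicate 4 the log2 fold change of Reln was -0.76. The exact permutation p was 0.00794, the smallest that 5 against 5 libraries can give; 102 of the 11202 genes tested (0.911%) likewise had no overlap between diets, where chance gives 0.794%. Over all genes the call depended on the tool: edgeR gave an unadjusted p of 0.000437 and an adjusted p of 0.972, and DESeq2 an adjusted p of 0.00525. The authors' deposited table lists Reln at a log2 fold change of -0.92 with an adjusted p of 0.00512, the 1 accession under 0.05 there. In the reelin list, which was not called (median -0.02, adjusted p = 0.0539), Crk was at -0.16 and Reln was the 1 gene that passed when adjusted over the list alone; the list was chosen from the title of the series, so this is not independent evidence. The receptor gene Vldlr (log2 fold change -0.14, SE 0.07, adjusted p = 0.972) and the adaptor gene Dab1 (-0.12, SE 0.13, adjusted p = 0.972) did not pass.

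**Figure D1:**
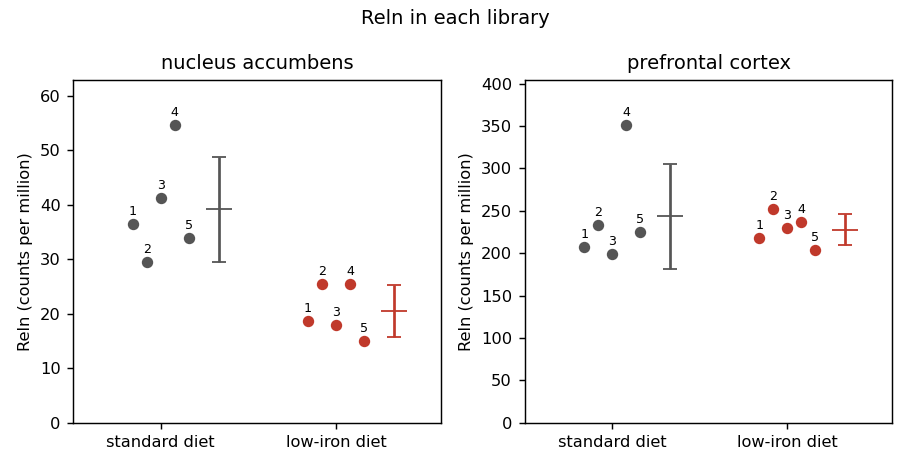
Reln level in CPM in each library of the nucleus accumbens (left) and prefrontal cortex (right), by diet; numbers are replicate numbers, and bars show the mean ± SD of 5 libraries. In the accumbens the low-iron libraries do not overlap the standard-diet libraries; in cortex they do, and standard-diet replicate 4 stands at 352 CPM.

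No gene passed in the accumbens with edgeR (0 of 11202). At an unadjusted p under 0.05 there were 454 (4.05%, where chance gives about 1 in 20), with 217 higher and 237 lower. DESeq2 called 1. Of the genes with the lowest p, none passing, those higher with the low-iron diet were the glycerol kinase gene Gk (log2 fold change 0.34, SE 0.07), Xkr6 (0.31), the dermatan sulfate epimerase gene Dse (0.43), the polycystin-2 gene Pkd2 (0.25) and the ubiquitin ligase gene Ube3a (0.22). Those lower, beside Reln, were the Wnt ligand gene Wnt9a (-1.17, SE 0.26), the autophagy gene Map1lc3a (-0.19), Hint1 (-0.24) and the beta-globin gene Hbb (-0.25), whose reads may be shared with near-identical globin copies. Wnt9a rested on few reads, at 1.45 CPM with the low-iron diet against 3.33 CPM, and was at -1.01 without standard-diet replicate 4.

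Of the 27 lists tested in the accumbens, camera with a preset correlation called 5. Nuclear genes of oxidative phosphorylation, which encode subunits of the respiratory chain and ATP synthase, were lower as a list, with 48 of 53 members below 0 and a median log2 fold change of -0.07 (adjusted p = 7.54e-09). With an estimated correlation the adjusted p = 0.427. Its members with the lowest p were Atp5me (-0.19) and Ndufb8 (-0.14), neither passing. Markers of striatal projection neurons, the main output neurons of this region, were higher as a list, with all 14 members above 0 and a median of 0.15 (adjusted p = 0.000875). This became adjusted p = 0.516 with an estimated correlation. Gnal stood at 0.15 and Strn at 0.17, without passing. Markers of D2 medium spiny neurons were above 0 in 7 of 7 members (median 0.11, adjusted p = 0.0365), and that list had adjusted p = 0.516 with an estimated correlation. Gucy1a1 stood at 0.19 and Gpr52 at 0.22. Glutamate and GABA receptor genes were above 0 in 22 of 32 members (median 0.09, adjusted p = 0.0215), which was adjusted p = 0.427 with an estimated correlation; Grik2 stood at 0.17 and Grm7 at 0.15. Circadian clock genes were above 0 in 10 of 14 members (median 0.11, adjusted p = 0.0371), which was adjusted p = 0.469 with an estimated correlation; Nr1d2 stood at 0.16 and Tef at 0.15. None of these members passed. With 1 library left out, between 1 and 15 lists were called; without low-iron replicate 1, or without standard-diet replicate 3, the oxidative phosphorylation list alone was called. In the neurotrophin list, which was not called (median -0.10, adjusted p = 0.0875), the receptor gene Ret (-0.77, SE 0.24) was the 1 gene that passed when adjusted over the list alone. With 27 lists adjusted in this way, such a pass can arise by chance.

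Lists of iron and dopamine genes were not called in the accumbens. The iron uptake, storage and export list had a median log2 fold change of -0.02 over 18 genes (adjusted p = 0.972), with Tfrc, the transferrin receptor, at 0.18 (0.0824 without low-iron replicate 5, and -0.0034 with library size as a covariate) and Fbxl5, an iron-sensing ubiquitin ligase subunit, at 0.12. The heme and iron-sulfur cluster list had a median of -0.05 over 20 genes (adjusted p = 0.102), with Iscu at -0.12 and Glrx5 at -0.11. Dopamine genes had a median of 0.09 over 12 genes (adjusted p = 0.173). With 1 library left out that median ran from 0.0125 (without standard-diet replicate 5) to 0.222 (without standard-diet replicate 2, adjusted p = 0.0425), and with a surrogate variable it was -0.0053. The list included the vesicular transporter gene Slc18a2, at 0.22. None of these members passed.

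**Figure D2:**
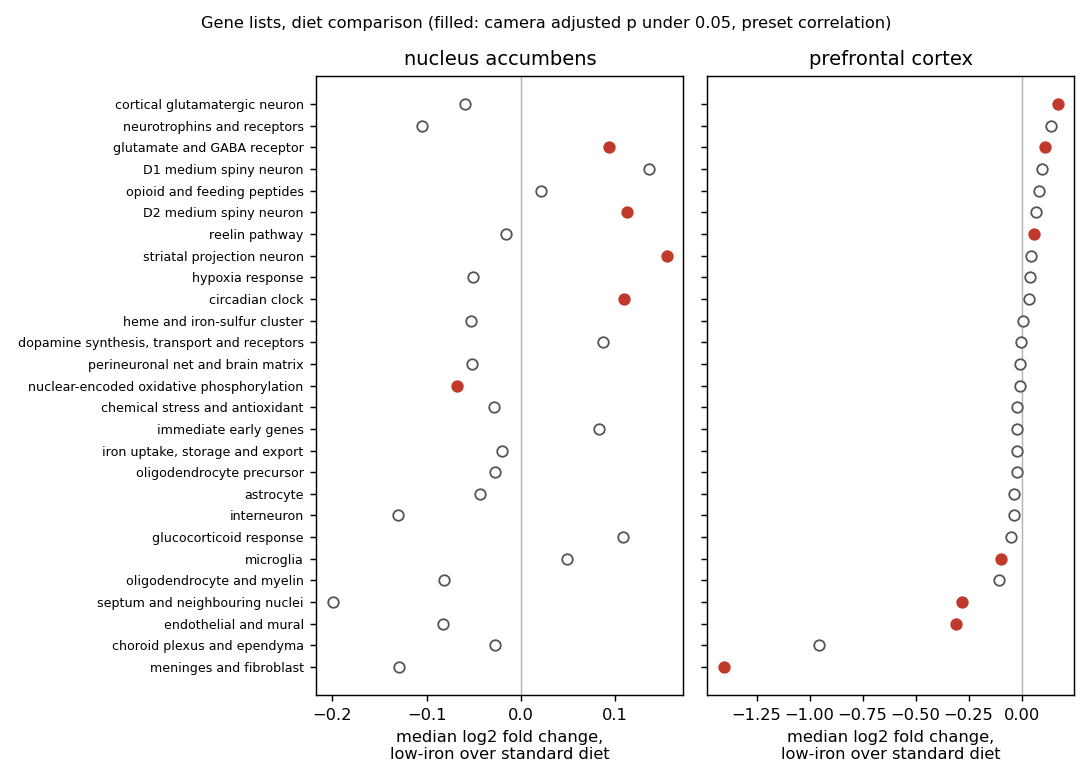
Median log2 fold change of each of 27 gene lists, low-iron over standard diet, in the nucleus accumbens (left) and prefrontal cortex (right); the horizontal scales differ. Filled points have a camera adjusted p under 0.05 with the preset correlation, 5 lists in the accumbens and 7 in cortex, and none of them passes with an estimated correlation.

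The same question was asked in the prefrontal cortex. Reln stood at 228 ± 18.2 CPM with the low-iron diet and 243 ± 62.0 CPM with the standard diet (SD, n = 5), a log2 fold change of -0.09 (SE 0.14) with an exact permutation p of 0.825. Without standard-diet replicate 4, which stood at 352 CPM, the log2 fold change was 0.08. Vldlr (0.08) and Dab1 (0.06) did not pass. Among the genes with the lowest p, none passing (adjusted p = 0.683 for each), those lower with the low-iron diet were the efflux pump gene Abcg2 (-0.42, SE 0.08), the organic anion transporter gene Slco2b1 (-0.24, SE 0.05), the phospholipid transfer gene Pltp (-0.28), Nipal2 (-0.44) and Slc40a1, which encodes the iron exporter ferroportin (-0.68, SE 0.16). Slc40a1 stood at 2.40 ± 0.429 CPM against 3.81 ± 0.340 CPM (SD, n = 5), with no overlap between diets (as for 128 genes, 1.10%, where chance gives 0.794%), and passed when adjusted over the list alone, the 1 member of the iron list to do so. Those higher were the protein kinase A gene Prkaca (0.22), the ephrin receptor gene Epha7 (0.31), Pik3r1 (0.22), Slc24a3 (0.23) and Guca2a (0.91). Guca2a lay near the read floor, at 1.27 CPM with the low-iron diet against 0.647 CPM. No gene passed with edgeR (0 of 11662), and DESeq2 called 0. An unadjusted p under 0.05 in edgeR was found for 699 (5.99%, where chance gives about 1 in 20), with 262 higher and 437 lower. The authors' deposited table likewise holds 0 accessions with an adjusted p under 0.05.

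Camera called 7 lists in the prefrontal cortex. Endothelial and mural cell markers were lower as a list, with 14 of 15 members below 0 and a median log2 fold change of -0.31 (adjusted p = 1.72e-07), which was adjusted p = 0.543 with an estimated correlation. Tek, an endothelial receptor gene, was at -0.36 and passed when adjusted over the list alone, and the tight junction gene Cldn5 was at -0.23. Markers of meninges and fibroblasts were below 0 in 10 of 10 members with a median of -1.40 (adjusted p = 0.00012), which was adjusted p = 0.598 with an estimated correlation; Col3a1 was at -1.79 and Slc6a13 at -1.34. Without standard-diet replicate 4 the median of the meninges list was -0.27 and that of the endothelial and mural list -0.21, with Col3a1 at -0.41 and Slc6a13 at -0.26. With a surrogate variable the meninges median was 0.0743. Microglia markers were below 0 in 13 of 15 members (median -0.10, adjusted p = 0.00176), which was adjusted p = 0.543 with an estimated correlation, and C1qb, a complement gene at -0.21, passed when adjusted over the list alone, while Trem2 was at -0.29. Markers of the septum and neighbouring nuclei were below 0 in 8 of 9 members (median -0.28, adjusted p = 0.0134), which was adjusted p = 0.543 with an estimated correlation; Prkcd was at -0.54 and Gnb4 at -0.21. Without standard-diet replicate 4 the septum median was -0.22 and Prkcd was at -0.26. Glutamate and GABA receptor genes (26 of 32 above 0, median 0.11, adjusted p = 8.04e-05) and cortical glutamatergic neuron markers (13 of 15 above 0, median 0.17, adjusted p = 0.00176) were higher as lists, each with adjusted p = 0.543 with an estimated correlation. Among them Gabra4 was at 0.20, Grik2 at 0.18, Neurod1 at 0.23 and Nrn1 at 0.20. Standard-diet replicate 4 stood at -0.65 for the cortical glutamatergic list, whose median was 0.076 without it (adjusted p = 0.0404) and -0.0061 with a surrogate variable. The reelin list was above 0 in 16 of 21 members (median 0.06, adjusted p = 0.0134) while Reln itself was not, and that list too had adjusted p = 0.543 with an estimated correlation. Its call was lost without standard-diet replicate 1 (adjusted p = 0.0560) or low-iron replicate 2 (adjusted p = 0.0612), and Crk, an adaptor gene of that list, was at 0.13. The iron list (median -0.02, adjusted p = 0.132), the heme list (median 0.01 with a camera direction below 0, adjusted p = 0.926) and the dopamine list (adjusted p = 0.926) were not called. Their members with the lowest p included the ferritin light chain gene Ftl1 (-0.20), Ppox (-0.15), Fech (-0.07), Slc18a2 (0.16) and Th (-1.27), which stood at 19.0 CPM in standard-diet replicate 4 and at most 4.16 CPM in the other standard-diet libraries (-0.44 without that library). None of these members passed over all genes.

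**Figure D3:**
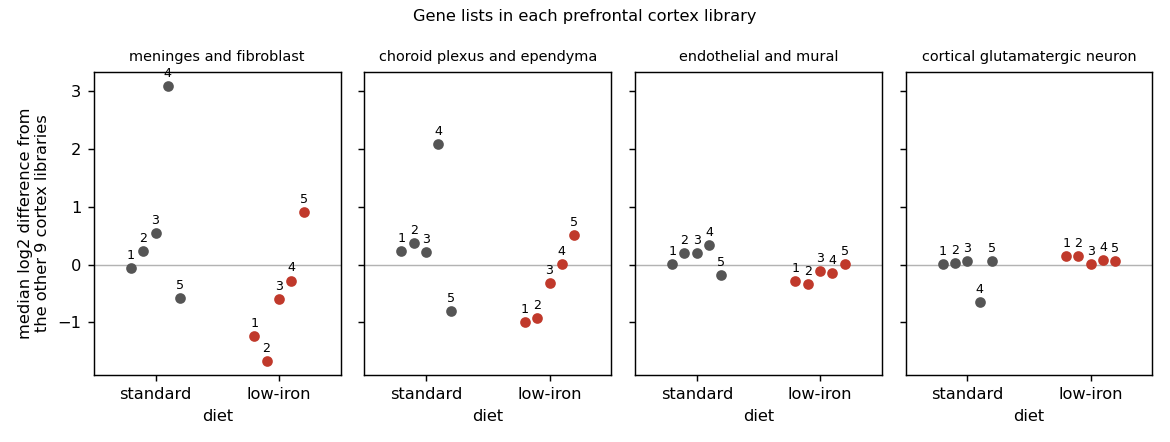
Median log2 difference of 4 gene lists in each prefrontal cortex library from the mean of the other 9 cortex libraries, by diet; numbers are replicate numbers. Standard-diet replicate 4 lies 3.09 above the others for the meninges list, 2.09 above for the choroid plexus list and at -0.65 for cortical glutamatergic markers.

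Whether the diet difference itself differed between regions was tested as an interaction. For Reln the accumbens log2 fold change was below that in cortex by -0.83 (SE 0.25, 95% interval -1.35 to -0.30), with an unadjusted p of 0.00365 in edgeR and an adjusted p of 0.818. Reln was chosen from the title of the series, so the unadjusted p is not independent evidence. No gene passed (0 of 11788), and DESeq2 called 0. An unadjusted p under 0.05 in edgeR was found for 632 (5.36%, where chance gives about 1 in 20). The lowest p belonged to Wnt9a (-1.54, adjusted p = 0.314), named here after its value was seen. Its level was low, at 1.45 CPM in the low-iron accumbens libraries. Camera called 6 lists, 0 of them with an estimated correlation (adjusted p = 0.602 for each) and 0 with fry. Oxidative phosphorylation (median -0.08, adjusted p = 5.59e-05), the reelin list (-0.13, adjusted p = 0.000817) and cortical glutamatergic markers (-1.07, adjusted p = 0.0156) were lower in the accumbens relative to cortex. Of the 15 cortical glutamatergic markers, 10 were measured in the accumbens diet comparison, with a median of -0.06 there (adjusted p = 0.5853). Markers of meninges (1.28), of endothelial and mural cells (0.24) and of microglia (0.10) were higher. Without standard-diet cortex replicate 4 the meninges median was 0.149 and its call was lost (adjusted p = 0.116), as was that of the cortical glutamatergic list (-0.92, adjusted p = 0.0690), and the endothelial and mural median was 0.137 (adjusted p = 0.0266) and the reelin median -0.07. The cortical glutamatergic call was also lost without accumbens standard-diet replicate 4 (-0.26, adjusted p = 0.125), accumbens low-iron replicate 1 (adjusted p = 0.0806) or cortex low-iron replicate 5 (adjusted p = 0.0504), and the microglia call without accumbens standard-diet replicate 1 (adjusted p = 0.0633). Across 11073 genes the log2 fold changes of the 2 regions had a Pearson r of 0.0596 and a Spearman rho of 0.0251; genes are not independent replicates. Without low-iron accumbens replicate 1 the r was -0.0157.

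The regions were compared under the standard diet. Of 11612 accessions 5462 passed, with 2675 higher in the accumbens and 2787 lower, and 1325 of these differed at least 2-fold. Six3, Lhx8 and Isl1, transcription factor genes of ventral forebrain neurons, had 0 reads in the 5 cortex libraries. Against a floor of 3 reads over the group they were 688-fold, 560-fold and 213-fold higher in the accumbens. The lower limits of the intervals on reads were 559-fold, 455-fold and 172-fold, in the same order. Gpr101 was also higher there (log2 fold change 7.71). Higher in cortex were Rspo2 (-7.65), Adra1d (-6.63), Cdh1 (-6.56) and Neurod6 (-5.95). Without cortex replicate 4 Cdh1 was at -5.38, without accumbens replicate 4 Neurod6 was at -7.24, and without accumbens replicate 3 Rspo2 was at -8.25. Striatal projection neuron markers rose in 13 of 13 members, with Gnal at 2.73 and Rgs9 at 5.73 (camera adjusted p = 3.35e-11; adjusted p = 0.181 with an estimated correlation). D2 markers rose in 7 of 7 (Drd2 4.27, Gpr6 5.81) and D1 markers in 5 of 6 (Drd1 4.61, Pdyn 4.15), and both lists had adjusted p = 0.146 with an estimated correlation. Cortical glutamatergic markers fell in 13 of 15, with Cux2 at -1.73 and Foxp2, higher in the accumbens, at 3.52 (adjusted p = 0.181 with an estimated correlation). Reln was lower in the accumbens, at -2.77 (adjusted p = 9.64e-07), and so was Dab1 (-1.22). Immediate early genes fell in 20 of 23 members, among them Dusp6 (-1.94) and Ier5 (-2.49), with adjusted p = 0.189 for the list with an estimated correlation. Myelin genes rose in 14 of 16, with Mag at 2.29 and Myrf at 1.83, and adjusted p = 0.181 for the list with an estimated correlation. Camera called 11 of 27 lists, 0 of them with an estimated correlation, and fry called 19. With an estimated correlation camera thus called no list even between regions, so its lack of calls says little about the diet lists. Fry called 0 lists in each diet comparison.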

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

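The tests of read depth, cortical tissue and interneurons for Reln, of striatal neurons and vessels in cortex replicate 4, and of tissue from outside the accumbens were chosen after the result was seen. Bootstrap intervals here and below resample the genes of a list, which are not independent replicates, and leave out the spread between libraries. Of 154 groups of 5 libraries examined, 12 held a library far from the other 4, where chance gives about 1 in 20, or 7.7. In the accumbens these were Ndufb8 at 184 CPM in standard-diet replicate 5 (nearest library 178) and Tfrc at 225 CPM in low-iron replicate 5 (nearest 175). In standard-diet cortex replicate 4 they were Reln at 352 CPM (nearest 234), Nipal2 at 15.5 CPM, Col3a1 at 459 CPM (nearest 73.0), Slc6a13 at 117 CPM (nearest 19.6), Th at 19.0 CPM (nearest 4.16) and the cortical glutamatergic list at -0.65. Other cortex libraries were Pltp at 159 CPM in low-iron replicate 3, Cldn5 at 119 CPM in standard-diet replicate 5, Col3a1 at 91.6 CPM in low-iron replicate 5 and C1qb at 52.4 CPM in standard-diet replicate 3. The Reln diet difference also differed between regions, by -0.83 on the log2 scale, when tested as a single gene (unadjusted edgeR p 0.00365, and adjusted p = 0.818 over all genes); the gene was chosen from the title of the series, so this is not independent evidence.

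Reln was lower in the low-iron accumbens libraries, which were also sequenced less deeply. With library size as a covariate its log2 fold change was -1.07 (SE interval -1.33 to -0.81), which argues against depth as the whole cause. Genes enriched in cortex at least as much as Reln had a median of -0.25 (bootstrap 95% interval -0.41 to -0.13, 44 genes). These genes were chosen with the same standard-diet accumbens libraries, which can shift their median upward. The interneuron list had a median of -0.13 (-0.38 to 0.04, 17 genes). Neither median reached the size of the Reln change, but intervals over genes leave out the spread between libraries. By these medians alone, neither a smaller cortical share nor fewer interneurons is excluded as the whole cause. The interneuron list also holds Gad1, Gad2 and Slc32a1, general genes of GABA neurons, so it cannot speak for interneurons alone. A smaller cortical share may account for part of the change. Standard-diet replicate 4 was highest for both Reln and the cortical gene Slc17a7 (325 CPM), and without it Reln was at -0.76. The other cortical markers were mixed: Tbr1, Nrn1 and Nptx1 were also highest in replicate 4, but Fezf2, Cux2, Rorb, Lmo4, Ccn2 and Foxp2 were not. DESeq2 called at least 1 gene in 21 of 100 splits of the accumbens libraries against 1 gene in the real one, and the highest other split had 930, so chance is not excluded for a call of that kind over all genes. An effect of the diet on Reln stays open.

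Standard-diet cortex replicate 4 stood apart, and the meninges, vessel and septum lists were lower with the low-iron diet. Without it the meninges list had a median of -0.27 (bootstrap interval -0.34 to -0.17), in line with extra meningeal tissue in that library, while the endothelial and mural list kept a median of -0.21 (-0.25 to -0.13), which leaves open how much of that part rests on this library. Genes enriched in the accumbens were 0.27 higher in it and those enriched in cortex lower (-0.37), the values set beforehand for accumbens tissue, but striatal projection neuron markers were at -0.17 (-0.26 to 0.04), against striatal neurons as their source. As many lists as the real 7 were called in 30 of 100 splits, with 12 the highest, so chance is not excluded. A diet effect on vessels remains untested beyond these values.

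In the accumbens the striatal projection neuron list was higher and the oxidative phosphorylation list lower with the low-iron diet. Ribosomal protein genes, which are short, had a median of -0.0540 (bootstrap interval -0.0676 to -0.0434) against -0.0684 for oxidative phosphorylation, between the bounds set beforehand, so a loss of short transcripts cannot be told apart from a change in that list. Of 10 lists of other cell types and nuclei, 9 had medians below 0, and the microglia list was at 0.0491 with an interval reaching down to -0.0068, so less tissue from outside the accumbens may also contribute. As many lists as the real 5 were called in 61 of 100 splits, with 12 the highest, and chance is not excluded. A diet effect is among the open explanations.

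For genes over all, the accumbens gave 0 in the real grouping (454 at an unadjusted p under 0.05 in edgeR, 1 by DESeq2) and 100 of 100 splits gave as many, the highest 879. A split calling that many points to a structure among the accumbens libraries, and what it separates was not tested. In cortex 100 of 100 splits reached the real 0 and the highest other also gave 0 (699 at an unadjusted p under 0.05 in edgeR, 0 by DESeq2). For the interaction the real value was 0, reached by 100 of 100, and the highest other 17 (632 at an unadjusted p under 0.05 in edgeR, 0 by DESeq2). Every split reaches a real count of 0, so for these comparisons the share of splits was fixed in advance and says nothing about chance. At an unadjusted p under 0.05 in edgeR, 38 of 100 splits gave at least as many genes as the real one in the accumbens. In cortex 16 of 100 did, the real one included in both. An r between regions as far from 0 as 0.0596 arose in 39 of 100 regroupings, the farthest at 0.192. The region comparison gave 5462 genes, reached by 1 of 100 splits, the real one, with 504 the highest other, so chance is excluded there.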

How the results depend on the processing

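Summing by symbol, the library-size covariate and the interaction lists with a library left out were chosen after the data were seen. The accumbens count was 0 except with DESeq2 (1 gene, Reln, log2 fold change -0.92, adjusted p 0.00525; edgeR alternatives 0.441 to 1.000). Reln in the accumbens ranged from -0.76 to -1.003 with a library left out. The cortex and interaction counts stayed at 0 in all settings run, and the region count lay between 4906 and 6294 with a library left out. The labels do not say whether a replicate number marks the same rat in both regions. Across regions, same-numbered libraries had an r of -0.04 to 0.07 with the standard diet, where 2 of 5 matched best with their own number. With the low-iron diet the r was 0.02 to 0.14 and 3 of 5 did, where chance gives about 1 of 5 for each diet. These values do not settle whether the number marks a rat, so it was used only in an alternative fit. In that fit the Reln interaction was -0.86 (edgeR adjusted p = 0.193). Across diets the r was -0.31 to 0.16. The replicate block gave 0 genes for each diet comparison and the interaction and 5188 for the regions, and raised the accumbens list count from 5 to 13. That count was 3 with the surrogate variable, 0 with an estimated correlation, 0 with fry and 1 to 15 with a library left out (1 without low-iron replicate 1 or standard-diet replicate 3). In cortex the count of 7 became 2, 0 and 0, and 6 to 11 with a library left out; the 6 interaction lists became 5 to 8. The cause was not tested.

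Directions reversed for 2 lists called in cortex (meninges and cortical glutamatergic, with the surrogate variable) and for values that did not pass. With the surrogate variable these were Reln (0.11), Dab1 (-0.0715) and Slc6a13 (0.0524) in cortex, the cortical glutamatergic (-0.0061), meninges (0.0743), iron (0.0099) and heme (-0.0336) lists in cortex, and the dopamine list in the accumbens (-0.0053). With the library-size covariate Tfrc in the accumbens was at -0.0034. The cortex dopamine list was at 0.0014 with DESeq2 size factors and between -0.0254 and 0.0176 with a library left out (above 0 without standard-diet replicates 1, 2 or 3 or low-iron replicates 1, 2 or 3). Without standard-diet cortex replicate 4, Reln was at 0.0766 (lowest with another left out -0.156), Dab1 at -0.0178 (highest 0.141) and the heme list at -0.0232 (-0.0004 without replicate 3, highest 0.0414). Between regions Cxcr4 was then at 0.108 (lowest -0.53) and Tp73 at 0.285 (0.0326 without accumbens replicate 2, lowest -0.406). The accumbens iron list was at 0.0342 without standard-diet replicate 5 (lowest -0.0491). The r between regions was -0.0157 without low-iron accumbens replicate 1. The cause was not tested. Depth limits low genes most: 3 reads are 0.691 CPM in the shallowest library.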

Other observations

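The test of olfactory bulb genes was written down before their values were seen, after other genes of the same library had prompted it. In standard-diet cortex replicate 4, Cdhr1 (log2 difference 4.37 from the other 4 standard-diet cortex libraries), Shisa8 (4.37), Eya2 (4.05) and Pbx3 (3.97) were among the 15 genes farthest above the others, together with Spp1 (5.18), Aqp1 (4.16) and Igf2 (3.99). Some of the former are known from the olfactory bulb, which lies in front of the prefrontal cortex, and the latter from meninges or choroid plexus.

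A hypothesis is that this library may hold some olfactory bulb tissue with its meninges. A list of 14 further genes of olfactory bulb neurons, without the genes that prompted it, had 9 measured members, with a median log2 difference of 1.84 (bootstrap 95% interval 0.81 to 2.54). In this library 8 of the 9 lay above each of the other 4. Slc17a6 stood at 25.4 CPM against a mean of 2.69, Doc2g at 54.9 against 10.7, Sp8 at 24.8 against 4.14, Dlx1 at 114 against 41.9 and Dcx at 166 against 56.0, while Sox11 stood at 8.06 against 7.64. The cortex libraries express all 9 measured members to some level, and the striatal list shares Meis2, and the labels describe the tissue as prefrontal cortex. Th and Reln, which bulb neurons also express, were highest of the standard-diet cortex libraries in this one, at 19.0 and 352 CPM.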
